A study of Rattus norvegicus with 60 samples.

How the data were processed

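The deposited table of 60 arrays, each with a signal and a detection p-value per gene, was used. Per the file headers the signal is the average intensity of a gene's beads, and the p-value is a detection p-value, as the authors deposited them. The values the authors processed are on a log2 scale, judged from the values set against log2 of the signals. The scaling behind them is not stated, so they served only as an alternative. Per the submitters' processing notes BeadStudio, lumi and limma were used, with versions not given in the sources used here. Groups and replicate numbers came from the labels, and each replicate number names a different rat.

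The table had 21794 lines, of which 2 were blank, leaving 21792 genes. In 1 array, replicate 3 of silica at 4 weeks, the signal column was displaced by 2 lines from gene line 17 on. It was moved back, which raised its correlation with the median array from 0.232 to 0.998 and with the authors' values from 0.143 to 0.996. All 60 columns of the authors' table were closest to their own array, with a lowest correlation of deviations of 0.689. The authors' table holds 12763 genes, among them all 12493 with a detection p-value of 0.01 or less on at least 1 array. The lowest median correlation of an array with the others was 0.990.

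Background was corrected by normexp with the mean and SD of negative controls inferred from the detection p-values, with an offset of 16, followed by quantile normalization and log2. The steps of the detection p-values imply 825 negative control types, and 576 genes whose p-values were no multiples of that step (tolerance 0.01), being combined from several probes, were left out of this inference. Genes were kept if detected at p under 0.05 on at least 4 arrays. Of several lines with 1 symbol the brightest stayed, which affected 146 symbols, and 13919 genes were tested. Names came from a table of rat genes of assembly GRCr8, used for names only: 16866 genes were named by gene identifier, 23 by accession and 4786 by the symbol in the file, and 117 stayed unnamed. In this step 10083 symbols were updated.

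Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit of 60 arrays with a mean for each of 10 groups and 50 residual degrees of freedom. Contrasts were silica against air at each time, the slope of that difference per doubling of weeks, the same slope in air rats, and an F-test of the differences among the 5 times. All adjusted p-values are Benjamini-Hochberg values over the genes tested, or over the 29 lists, with a call at an adjusted p under 0.05. A few counts in the text are rounded to 2 digits (as in 2.3e+02) and stand exactly in the tables. The stricter rule was an adjusted p under 0.01 and a 1.5-fold change. Gene lists with at least 4 measured members were tested with camera at its preset correlation of 0.01 and with an estimated correlation, and with fry. List means per rat were compared by an exact permutation test over 495 splits, whose smallest p is 0.00202. Counts adjusted over the list alone use only the p-values of that list's members. Other steps used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

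The samples, the contrasts, the 29 lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. The antioxidant list also holds subunits of the superoxide-producing NADPH oxidases. Some lists share members, so lists that passed are not all separate findings. Examples are Ccl17 (chemokines and alternative activation), Spp1 and Mmp12 (macrophage and matrix) and Atp6v0d2 (macrophage and lysosome). The lists were chemokines and cytokines, neutrophil, macrophage, T cell, B cell and plasma cell, NK and cytotoxic cell and mast cell markers, alternative activation, complement, antioxidant, matrix and remodelling, type II cell and surfactant, lipid and cholesterol, type I cell, club and secretory cell, ciliated cell, endothelial, mesothelial, cardiac muscle, skeletal muscle, adipocyte, erythroid, cell cycle, interferon-stimulated, MHC class II, lysosome, inflammasome and NF-kB, clock and immediate early genes. Named genes were, at each time, the 10 largest rises and 5 largest falls among genes that passed with every silica rat beyond the air mean, the 10 most positive and 10 most negative slopes of the silica effect, the 5 most positive and 5 most negative slopes in air rats, up to 4 members per list by adjusted p (or the 2 brightest where none passed), and 22 preset genes. Of the preset genes C3 was not measured. The result of 1 list member is not reported here.

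The alternatives fixed then were no background correction, normexp without controls (offset 50), median scaling, cyclic loess, the authors' values, no detection filter, detection on at least 30 arrays, the mean of a gene's lines, an intensity trend with robust eBayes, array weights, each time fitted alone, the replicate number as a block, stricter thresholds, leaving out each rat, leaving out each week of the trend, an estimated correlation and fry. Added after seeing the data were the run of arrays in the deposited order as a block, leaving out the 5 arrays of the run with the fewest detected genes, leaving out the 5 air arrays of the run with the highest silica-response genes, and covariates for cardiac markers, for Nr1d1 and Bmal1, and for 12 liver genes, all 12 of which were measured. Genome coordinates were not used here. The fits were tested on simulated data with independent noise after they had first been run on the arrays: of genes changed 1.5-fold, 91.0% were recovered at 1, 2, 4 and 8 weeks, 94.0% at 16 weeks and 82.1% for the slope and the F-test. The false calls were 7 to 18 of 13919 genes. Of 5 lists shifted by 0.4, 5 were recovered, and of 21 unshifted lists 1 was called.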

Results

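Gene expression was measured in the lungs of 60 male rats of the inbred Fischer strain on Illumina BeadChip arrays, 1 array per rat. Of these, 40 rats had inhaled crystalline silica, a mineral dust that injures the lung, at 15 mg/m3 for 6 hours a day on 5 days, and 20 rats had breathed filtered air. Separate animals were studied 1, 2, 4, 8 and 16 weeks after exposure, 8 silica and 4 air rats at each time, so that every time had its own air controls. In the deposited order of arrays, air arrays lay in runs 1, 3, 5 and 6 only, at every time. Runs 2, 4, 7 and 8 held silica arrays alone, so silica was partly confounded with run in the same way at each time. The median signal of an array lay between 60.2 and 97.8, and a median of 12082.5 genes was detected per array (11225 to 12594). The precision of all values is limited by the number of arrays, above all by the 4 air arrays at each time. Changes are given as log2 of silica over air ± standard error for 8 silica and 4 air rats. Each gene named as risen or fallen in silica rats had a limma adjusted p under 0.05. Unless another number stands beside it, 8 of 8 silica rats lay beyond the air mean in that direction. Counts of list members that rose or fell rest on direction and adjusted p alone, with no condition on single rats.

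The first question was what the lung expressed 1 week after exposure. The largest rise was that of Cxcl6, a chemokine that attracts neutrophils, by 2.82 ± 0.23, detected in 1 of 4 air rats and 8 of 8 silica rats. Slc26a4, the anion exchanger pendrin, rose by 2.18 ± 0.31 (4.52-fold) and Cd177, a neutrophil surface protein, by 2.06 ± 0.23 (4.17-fold). Next came Lcn2, which binds bacterial iron carriers (1.94 ± 0.20, 3.83-fold), and Cxcl1, another neutrophil chemokine (1.89 ± 0.17, 3.72-fold). Mmp12, the macrophage elastase, rose by 1.68 ± 0.30, Rnase9 by 1.66 ± 0.16 and Noxo1, which organizes a superoxide-producing NADPH oxidase, by 1.62 ± 0.18 (3.08-fold). Ccl2, which attracts monocytes, rose by 1.57 ± 0.21 and Itih1 by 1.29 ± 0.17 (detected in 3 of 4 air rats). The largest falls were those of Nr1d1, a repressor in the circadian clock (-1.57 ± 0.35), Dlk1, a membrane protein related to Notch ligands (-1.44 ± 0.25, detected in 7 of 8 silica rats), Col4a3, a basement membrane collagen (-0.84 ± 0.17), LOC317070 (-0.81 ± 0.22) and Sirpb3 (-0.80 ± 0.21, also detected in 7 of 8). In all, 532 of 13919 genes passed, 373 of them higher, and 73 also met an adjusted p under 0.01 and a 1.5-fold change. The count was 141 with arrays scaled by their medians, 2.3e+02 without air replicate 3 and 250 without air replicate 4. LOC317070 (-0.73 and -0.78) and Sirpb3 (-0.74 and -0.69) did not pass without air replicate 3 or without air replicate 4. LOC317070 also did not pass when the 1 week groups were fitted alone.

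By gene group, 12 of 31 chemokines and cytokines rose at 1 week, 18 adjusted over the list alone, among them Ccl3, a macrophage chemokine (0.93 ± 0.14). The group moved up as a whole (camera adjusted p = 3.01e-16, and adjusted p = 0.00556 with an estimated correlation). Ccl5, a T cell chemokine named after its value was seen, was the 1 member that fell (-0.32 ± 0.08). Of 24 macrophage markers 12 rose, 14 adjusted over the list alone, such as Chi3l1, a chitinase-like protein (0.83 ± 0.12), and Atp6v0d2, a proton pump subunit (1.22 ± 0.19; camera adjusted p = 1.99e-10, and adjusted p = 0.0193 with an estimated correlation). Alternative activation genes rose in 4 of 9 cases, 5 adjusted over the list alone, with Retnla, a secreted product of alternatively activated macrophages, 2.39-fold higher (standard error 0.25 on log2) and Arg1, which breaks down arginine, at 0.66 ± 0.12 (adjusted p = 0.006 with an estimated correlation). Complement genes (6 of 19 rose, 9 adjusted over the list alone), antioxidant genes (5 of 26, 7 adjusted over the list alone), MHC class II genes (6 of 8, 7 adjusted over the list alone), lysosome genes (8 of 22, 12 adjusted over the list alone) and cell cycle genes (6 of 25, 12 adjusted over the list alone) also moved up, with adjusted p = 0.0253, 0.0311, 0.0178, 0.0243 and 0.0311 with an estimated correlation. Some complement genes are also liver products. The mean of 12 liver genes was 0.67 higher in silica rats at 1 week (exact permutation p = 0.103, 7 of 8) and 1.05 higher at 4 weeks (p = 0.135, 6 of 8). With it as a covariate, chosen after seeing the data, complement genes at 1 week still passed (adjusted p = 0.0374 with an estimated correlation). Examples were C1qc, a chain of the first complement component (0.53 ± 0.09), the metal-binding Mt1 (0.77 ± 0.08), and the mitochondrial superoxide dismutase Sod2 (0.80 ± 0.10). Surfactant and type II cell genes (4 of 15 rose, 9 adjusted over the list alone) and lipid genes (5 of 28, 7 adjusted over the list alone) moved up as well (adjusted p = 0.0243 and 0.0304 with an estimated correlation). Type II cell genes called higher, named after their values were seen, included Ctsh (0.37), Lamp3 (0.32) and Muc1 (0.40). In the same list the surfactant protein gene Sftpc did not pass, and Dlk1 was called lower (-1.44). Endothelial markers moved down, 2 of 12 falling, 8 adjusted over the list alone (adjusted p = 0.00658 with an estimated correlation). The 2 were Tie1, an endothelial receptor kinase (-0.29 ± 0.06) and Emcn, an endothelial sialomucin (-0.25 ± 0.07). The call of Tie1 ended with median scaling (-0.31) and without air replicate 4 (-0.22). That of Emcn ended with median scaling (-0.25), without air replicates 2 (-0.25), 3 (-0.23) or 4 (-0.24) and without silica replicates 1 (-0.23) or 5 (-0.25). Of 29 lists 20 passed camera with its preset correlation and 11 with an estimated correlation.

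The second comparison asked how the lung differed from air controls at 2 weeks. Several of the same genes led: Cd177 rose by 2.42 ± 0.23 (5.37-fold), Slc26a4 by 2.36 ± 0.31 (5.14-fold), Lcn2 by 2.32 ± 0.20 (4.99-fold), Mmp12 by 2.19 ± 0.30, Cxcl6 by 2.13 ± 0.23 (detected in 3 of 4 air rats) and Ccl2 by 1.51 ± 0.21. C2cd4b (1.65 ± 0.15), Ceacam4 (2.83-fold, standard error 0.12 on log2) and Retnla (1.48 ± 0.25, 2.78-fold) were among the 10 largest rises. Nr1d1 was higher here, by 1.90 ± 0.35, where it was lower at 1 week. Dlk1 fell by -2.55 ± 0.25, to near background in silica rats, 3 of 8 of which had it detected. Tac1, the precursor of the neuropeptide substance P, fell by -1.15 ± 0.14 (detected in 7 of 8), the steroid-metabolizing Akr1c3 by -1.14 ± 0.25 (detected in 5 of 8), Ass1, an enzyme of arginine synthesis, by -0.86 ± 0.10 and the methyltransferase Inmt by -0.84 ± 0.19. All 8 measured MHC class II genes rose, 8 adjusted over the list alone, for example RT1-DMa (0.42 ± 0.07) and RT1-Da (0.30 ± 0.05), genes of antigen presentation whose calls ended with median scaling at 0.26 and 0.11 (camera adjusted p = 1.78e-13, and adjusted p = 0.00913 with an estimated correlation). Chemokines and cytokines rose in 11 of 31 cases, 14 adjusted over the list alone (adjusted p = 0.0419 with an estimated correlation). Of 29 lists 15 passed camera with the preset correlation, and these 2 alone passed with an estimated correlation. In the lists whose call was lost, 11 of 24 macrophage markers (12 adjusted over the list alone) rose, with adjusted p = 0.0873 with an estimated correlation. Cell cycle genes, of which 8 of 25 rose (11 adjusted over the list alone), also had adjusted p = 0.0873 with an estimated correlation.

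At 2 weeks 1304 genes passed, 667 higher and 637 lower, and 113 passed the stricter rule. The count moved with the settings: it was 692 with median scaling, 746 with array weights, 413 when the 2 week groups were fitted alone, 469 without air replicate 4 and 538 without air replicate 3. It was 104 with Nr1d1 and Bmal1, the core clock activator, as covariates, and 476 without the 5 air arrays of 1 run of the deposited order in which silica-response genes were highest, both chosen after seeing the data. With median scaling 24.4% of the called genes were higher, against 51.2% as reported. The share went both ways. It was 48.0% with the authors' values, 47.1% without air replicate 2 and 49.7% without silica replicate 1 or 6. It was 61.4% with cyclic loess, 59.5% with array weights, 66.8% with the 2 week groups fitted alone, 61.3% without air replicate 3 and 63.1% without air replicate 4. With Nr1d1 and Bmal1 as covariates it was 78.8%, and without the 5 air arrays of 1 run 64.5%.

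The comparison at 4 weeks asked whether the response persisted. Cxcl6 rose by 2.93 ± 0.23 (detected in 2 of 4 air rats), Slc26a4 by 2.60 ± 0.31 (6.07-fold), Lcn2 by 2.47 ± 0.20 (5.56-fold), Cd177 by 2.20 ± 0.23, Mmp12 by 2.09 ± 0.30, Noxo1 by 1.71 ± 0.18, Rnase9 by 1.70 ± 0.16, Ccl2 by 1.64 ± 0.21 and the membrane protein Tmem45b by 1.58 ± 0.14 (detected in 3 of 4 air rats). Falls were led by Dlk1 (-1.89 ± 0.25, detected in 4 of 8 silica rats), Nr1d1 (-1.68 ± 0.35) and Tac1 (-1.09 ± 0.14, detected in 7 of 8). Cox6a2, a muscle form of a respiratory chain subunit (1.78 ± 0.58, detected in 2 of 4 air rats), Slc51a, a steroid transporter subunit (-1.02 ± 0.32), and Fam180a (-0.84 ± 0.26) were also among the largest changes. Their calls ended without any 1 of 8, 8 and 7 of the 12 rats. Over all 12 omissions the values ranged from 1.40 to 2.00, from -1.17 to -0.79 and from -0.95 to -0.69. Club, mucous and secretory cell genes moved up, 4 of 13 rising, 7 adjusted over the list alone (camera adjusted p = 5.71e-11, and adjusted p = 0.0157 with an estimated correlation). Among the 4 was Cldn10, a tight junction protein (1.01 ± 0.10). The others called were Slc26a4 and Lcn2, both among the largest rises above, and Pigr (0.62). The club cell gene Scgb1a1 did not pass. Within groups the mean of these club, mucous and secretory cell genes followed that of cardiac muscle markers (r = 0.757 over 60 rats), which at 4 weeks was 1.37 higher in silica rats (exact permutation adjusted p = 0.188), while the mean of mesothelial markers was -0.47 lower (adjusted p = 0.0586). Neither passed. With the cardiac mean as a covariate, chosen after seeing the data, the list mean was 0.72 higher in place of 1.23 (camera adjusted p = 5.62e-07, and adjusted p = 0.031 with an estimated correlation). Chemokines and cytokines rose in 11 of 31 cases, 15 adjusted over the list alone (adjusted p = 0.0252 with an estimated correlation). These were the 2 of 18 lists passing camera that also passed with an estimated correlation. MHC class II genes, of which 3 of 8 rose (5 adjusted over the list alone), had adjusted p = 0.0874 with an estimated correlation. In all 924 genes passed, 398 higher and 526 lower, and 80 passed the stricter rule. The count was 444 when the 4 week groups were fitted alone, 241 without air replicate 3, 353 without air replicate 4 and 1453 without air replicate 2. It was 438 with Nr1d1 and Bmal1 and 574 with a mean of liver genes as covariates, chosen after seeing the data. With median scaling 9 lists passed camera, and 11.4% of called genes were higher in place of 43.1%. That share was 56.0% with cyclic loess, 52.9% with the 4 week groups fitted alone, 61.8% without air replicate 3 and 53.2% with the cardiac mean as a covariate.

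At 8 weeks, the question was whether the response grew. Cxcl6 rose by 3.46 ± 0.23 (detected in 3 of 4 air rats), Slc26a4 by 3.10 ± 0.31 (8.59-fold), Lcn2 by 2.67 ± 0.20 (6.37-fold), Ccl2 by 2.47 ± 0.21 (5.54-fold) and Ccl7, another monocyte chemokine, by 2.14 ± 0.19 (4.42-fold). Mmp12 (2.44 ± 0.30), Cd177 (2.39 ± 0.23), Tmem45b (2.20 ± 0.14), Ceacam4 (2.18 ± 0.12) and Rnase9 (2.12 ± 0.16) completed the 10 largest rises. The largest falls were those of Dlk1 (-2.49 ± 0.25, detected in 1 of 8 silica rats), Nr1d1 (-1.79 ± 0.35), Tac1 (-1.32 ± 0.14, detected in 6 of 8), Akr1c3 (-1.20 ± 0.25; at least 1.96-fold, since it was detected in 0 of 8 silica rats) and the calcium-binding Tesc (-1.03 ± 0.13). Spp1, the secreted matrix protein osteopontin, rose by 1.24 ± 0.36, but its call ended with median scaling (1.24), when the 8 week groups were fitted alone (1.24), without air replicate 2 (0.89), without air replicate 3 (1.00) and without silica replicate 8 (1.02). The interleukin gene Il1b rose by 0.46 ± 0.11, with the call lost under median scaling (0.42).

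Neutrophil markers moved as a group at 8 weeks, 6 of 13 rising, 6 adjusted over the list alone, with the calcium-binding S100a8 at 1.14 ± 0.14 and the chemokine receptor Cxcr2 at 0.52 ± 0.13 (camera adjusted p = 3.25e-06, and adjusted p = 0.00433 with an estimated correlation). Their mean had been higher in 8 of 8 silica rats at 1, 2 and 4 weeks too, by 0.25, 0.27 and 0.26 (exact permutation adjusted p = 0.00651, 0.00586 and 0.0146, but adjusted p = 0.0622, 0.183 and 0.112 with an estimated correlation). Chemokines and cytokines rose in 19 of 31 cases, 20 adjusted over the list alone (adjusted p = 0.00411 with an estimated correlation). Macrophage markers (13 of 24 rose, 16 adjusted over the list alone), alternative activation genes (5 of 9, 6 adjusted over the list alone), complement genes (8 of 19, 9 adjusted over the list alone) and cell cycle genes (14 of 25, 16 adjusted over the list alone) moved up, with adjusted p = 0.00893, 0.00433, 0.00893 and 0.00752 with an estimated correlation. Rrm2, needed for DNA synthesis, rose by 0.95 ± 0.14, Ccnb2, a mitotic cyclin, by 0.73 ± 0.10 and C1qa by 0.57 ± 0.09. Lipid (9 of 28 rose, 14 adjusted over the list alone), MHC class II (5 of 8, 7 adjusted over the list alone) and lysosome genes (10 of 22, 13 adjusted over the list alone) had adjusted p = 0.0215, 0.0231 and 0.0269 with an estimated correlation. Markers of the alveolar wall moved down: 6 of 12 type I cell markers fell, 7 adjusted over the list alone (adjusted p = 0.00433 with an estimated correlation), as did 5 of 12 endothelial markers, 10 adjusted over the list alone (adjusted p = 0.00893 with an estimated correlation). Tie1 fell by -0.37 ± 0.06. Of 29 lists 17 passed camera and 11 with an estimated correlation. In all 1241 genes passed, 663 higher and 578 lower, and 174 changed at least 1.5-fold. The count was 422 with median scaling, 778 with these groups fitted alone, 701 without air replicate 3 and 720 with Nr1d1 and Bmal1 as covariates, chosen after seeing the data.

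The last time asked what marked the lung 16 weeks after exposure. Slc26a4 rose by 3.35 ± 0.31 (10.2-fold), Spp1 by 3.29 ± 0.36 (9.76-fold), Ccl7 by 3.24 ± 0.19 (9.47-fold), Mmp12 by 3.05 ± 0.30 (8.31-fold), Ccl2 by 3.02 ± 0.21 (8.11-fold) and Cxcl6 by 2.95 ± 0.23 (7.73-fold). Retnla (2.86 ± 0.25, 7.25-fold), Lcn2 (2.45 ± 0.20), the airway peroxidase Lpo (2.33 ± 0.14, detected in 3 of 4 air rats) and Cxcl11, a chemokine induced by interferon (2.28 ± 0.32), completed the 10 largest rises. The 5 largest falls were heart muscle genes, the myosin chains Myh6 (-5.17 ± 1.31, detected in 3 of 8 silica rats) and Myl7 (-4.82 ± 1.21, detected in 4 of 8), the troponins Tnni3 (-3.20 ± 0.85) and Tnnt2 (-3.12 ± 0.91), and Csrp3 (-2.96 ± 0.74, detected in 1 of 8). In all 3159 genes passed, 1459 higher and 1700 lower, and 392 passed the stricter rule. The balance depended on the setting: 46.2% of the called genes were higher, against 39.9% with median scaling and 52.0% with cyclic loess. With covariates chosen after seeing the data it was 43.2% (cardiac mean) and 50.9% (Nr1d1 and Bmal1). The count was 2005 with median scaling and 1636 with Nr1d1 and Bmal1 as covariates, chosen after seeing the data.

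**Figure D1:**
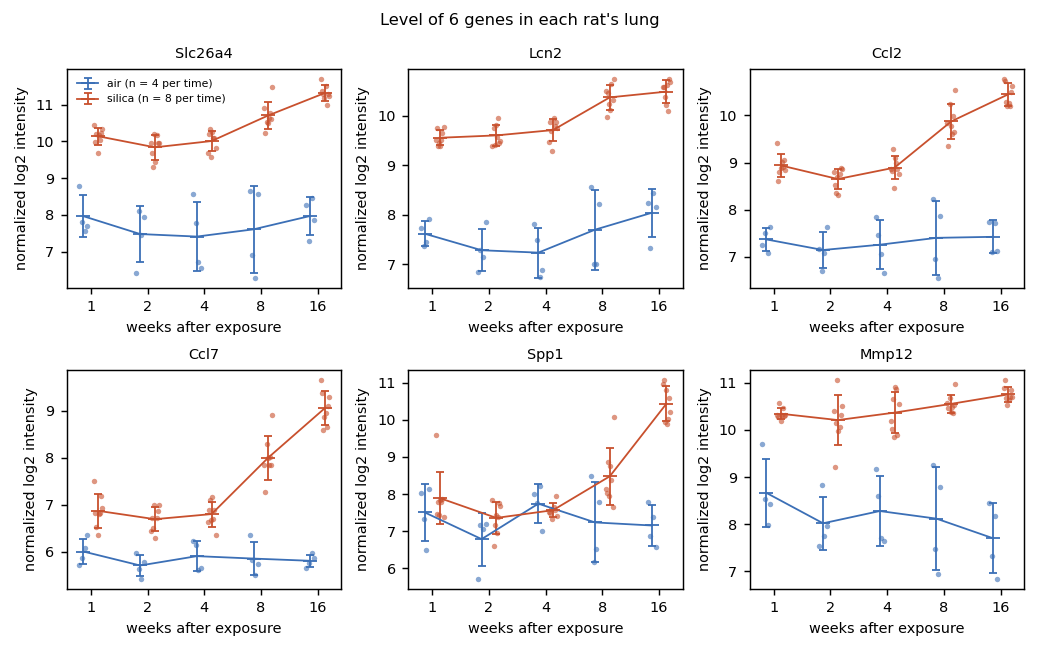
Normalized log2 intensity of Slc26a4, Lcn2, Ccl2, Ccl7, Spp1 and Mmp12 in each rat (points) against weeks after exposure, with the mean ± SD of air rats (blue, n = 4) and silica rats (orange, n = 8). Slc26a4, Lcn2, Ccl2 and Mmp12 were higher in silica rats at every time, while the difference in Spp1 was 3.29 at 16 weeks.

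Immune gene groups were also tested at 16 weeks. Chemokines and cytokines rose in 21 of 31 cases, 21 adjusted over the list alone (camera adjusted p = 1.67e-13, and adjusted p = 0.00448 with an estimated correlation). In this list 3 genes fell: Il33, an epithelial alarm cytokine (-0.37 ± 0.06), Ccl21 (-0.44 ± 0.09) and Ccl5 (-0.32 ± 0.08), named after their values were seen. Neutrophil markers (7 of 13 rose, 10 adjusted over the list alone), macrophage markers (18 of 24, 19 adjusted over the list alone), alternative activation genes (6 of 9, 6 adjusted over the list alone) and complement genes (14 of 19, 15 adjusted over the list alone) had adjusted p = 0.00448, 0.00611, 0.00611 and 0.00448 with an estimated correlation. S100a8 rose by 1.48 ± 0.14, Chi3l1 by 1.55 ± 0.12, Arg1 by 1.05 ± 0.12, the macrophage chemokine Ccl17 by 0.95 ± 0.12 and the complement regulator Cfi by 2.01 ± 0.23. Cell cycle genes rose in 19 of 25 cases, 19 adjusted over the list alone, with the cell division kinase Cdk1 at 0.85 ± 0.11 (adjusted p = 0.00922 with an estimated correlation). MHC class II (6 of 8 rose, 7 adjusted over the list alone), lysosome (14 of 22, 15 adjusted over the list alone) and lipid genes (13 of 28, 15 adjusted over the list alone) had adjusted p = 0.0459, 0.0239 and 0.0184 with an estimated correlation. Inflammasome and NF-kB genes rose in 8 of 17 cases, 10 adjusted over the list alone, for example the endotoxin receptor Cd14 (0.63 ± 0.09; camera adjusted p = 0.00067, but adjusted p = 0.0729 with an estimated correlation). Antioxidant genes went both ways, 10 of 26 up and 5 down, 10 and 5 adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.0661 with an estimated correlation). Mt1 rose by 1.33 ± 0.08, Sod2 by 1.07 ± 0.10 and the heme-degrading Hmox1 by 1.12 ± 0.16. Noxo1, a member of the list that serves to make superoxide, rose by 1.78 ± 0.18. The 5 that fell, named after their values were seen, were Gpx3 (-0.34 ± 0.06), Sod3 (-0.26 ± 0.05), Prdx6 (-0.19 ± 0.05), Gpx4 (-0.21 ± 0.06) and Gstp1 (-0.30 ± 0.09). Immediate early genes rose in 6 of 14 cases, 6 adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.187 with an estimated correlation). Single members that fell in lists that rose, also named after their values were seen, were Prtn3 (-0.29 ± 0.09), Chit1 (-0.37 ± 0.08), Ctsl (-0.29 ± 0.05), Rela (-0.25 ± 0.07) and Klf4 (-0.28 ± 0.10).

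At 1, 2, 4 and 8 weeks the mean of NK and cytotoxic cell markers differed by -0.19, -0.16, -0.13 and -0.14. The exact permutation adjusted p was 0.00651, 0.00976, 0.0842 and 0.0508. For T cell markers the differences were -0.12, 0.0053, -0.12 and -0.17, with exact permutation adjusted p = 0.00976, 0.943, 0.188 and 0.00451. None of these passed camera with an estimated correlation. At 16 weeks the lymphocyte lists were mixed. NK and cytotoxic cell markers fell in 8 of 13 cases, 8 adjusted over the list alone, including the protease Gzma (-0.51 ± 0.10) and the receptor Klrb1a (-0.53 ± 0.09; camera adjusted p = 0.000262, adjusted p = 0.0942 with an estimated correlation), while Klrb1b rose (0.42 ± 0.10, named after its value was seen). Of 17 T cell markers 2 fell and none rose, 2 and 0 adjusted over the list alone: Cd8a (-0.45 ± 0.09) and Cd8b (-0.39 ± 0.09), chains of the cytotoxic T cell coreceptor (camera adjusted p = 0.354, adjusted p = 0.753 with an estimated correlation). Of 12 B cell and plasma cell markers 2 rose, the immunoglobulin genes Ighg (1.36 ± 0.25) and Jchain (0.81 ± 0.20), and 3 fell, among them the B cell surface genes Ms4a1 (-0.57 ± 0.14) and Cd79b (-0.51 ± 0.14), 2 and 3 adjusted over the list alone. The median change over the 12 was -0.06 and the mean 0.04 (camera adjusted p = 0.78, adjusted p = 0.86 with an estimated correlation). The call of Cd79b ended without the 5 air arrays of 1 run of the deposited order. Mast cell markers (3 of 10 rose, 3 adjusted over the list alone), interferon-stimulated genes (2 of 19, 2 adjusted over the list alone: Ifit1, 0.64 ± 0.13, detected in 2 of 4 air rats, and Ifit3, 0.64 ± 0.16) and adipocyte markers (1 of 4, 1 adjusted over the list alone: Cfd, 0.30 ± 0.08, whose call ended with median scaling at 0.22) had camera adjusted p = 0.274, 0.477 and 0.273, and adjusted p = 0.553, 0.794 and 0.435 with an estimated correlation. The mast cell genes were Hdc (0.29 ± 0.08), Cpa3 (0.54 ± 0.17, 7 of 8) and Tpsb2 (detected in 0 of 4 air and 3 of 8 silica rats, so that no size is given), and none kept its call throughout. The call of Hdc ended with median scaling (0.26) and without air replicate 4 (0.21). That of Cpa3 ended without air replicate 3 (0.49) and without silica replicates 1 (0.46) or 2 (0.44), and that of Tpsb2 without any 1 of 5 rats.

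Structural lists at 16 weeks parted. Endothelial markers fell in 10 of 12 cases, 11 adjusted over the list alone, with the endothelin receptor Ednrb at -0.43 ± 0.06 and von Willebrand factor Vwf at -0.42 ± 0.07 (camera adjusted p = 9.70e-09, and adjusted p = 0.00448 with an estimated correlation). Type I cell markers fell in 7 of 12 cases, 7 adjusted over the list alone, such as Clic5 (-0.47 ± 0.07) and the caveolar Cav2 (-0.47 ± 0.09; adjusted p = 0.00891 with an estimated correlation). Type II cell and surfactant genes rose in 7 of 15 cases and 1 fell, 7 and 2 adjusted over the list alone, with Sftpd, surfactant protein D, at 0.74 ± 0.14 and Dlk1 at -2.47 ± 0.25, detected in 1 of 8 silica rats (camera adjusted p = 0.00454, adjusted p = 0.16 with an estimated correlation). Ciliated cell genes fell in 6 of 15 cases, 9 adjusted over the list alone (camera adjusted p = 0.00113, adjusted p = 0.393 with an estimated correlation). The camera call of the ciliated cell genes ended with the cardiac mean as a covariate, chosen after seeing the data (adjusted p = 0.717, mean -0.0638). Matrix and remodelling genes went both ways, 6 of 35 up and 11 down, 8 and 13 adjusted over the list alone. The proteases Mmp12 and Mmp7 (1.31 ± 0.17, at least 1.95-fold, since it was detected in 0 of 4 air rats) rose and the matrix protein Postn fell by -0.47 ± 0.06. The median of the matrix list was -0.13 and its mean 0.18, with the list mean higher in 8 of 8 silica rats (exact permutation p = 0.00202). Camera leaned down (adjusted p = 0.769, and adjusted p = 0.841 with an estimated correlation). The mean and its permutation test rest largely on Mmp12 and Spp1, list members among the largest rises above that also stand in the macrophage list. Club, mucous and secretory cell genes rose in 5 of 13 cases and 1 fell, 5 and 2 adjusted over the list alone, with median -0.43 and mean -0.04 while camera leaned up (adjusted p = 0.0867, and adjusted p = 0.435 with an estimated correlation). With the cardiac mean as a covariate the mean of the club, mucous and secretory cell genes was 0.78 and the list passed (camera adjusted p = 4.1e-05, and adjusted p = 0.0381 with an estimated correlation). The gene that fell was Cyp4b1, an airway P450 enzyme (-0.43 ± 0.07). Of 7 mesothelial markers 1 fell, the keratin Krt19 (-0.23 ± 0.07; call ended with median scaling at -0.27 and without air replicate 4 at -0.18), 1 adjusted over the list alone (camera adjusted p = 0.477, adjusted p = 0.753 with an estimated correlation). Of 29 lists 18 passed camera and 11 with an estimated correlation.

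Heart muscle transcripts moved with these groups at 16 weeks. Of 10 cardiac muscle markers 8 fell, 8 adjusted over the list alone, and their mean was -2.21 lower with 0 of 8 silica rats above the air mean (exact permutation p = 0.00202; camera adjusted p = 0.00111, adjusted p = 0.246 with an estimated correlation). At 1, 2, 4 and 8 weeks the same mean differed by -0.89, 0.63, 1.37 and -0.94, and no marker passed. Of 6 skeletal muscle markers Tnni2 rose (0.30 ± 0.08, detected in 1 of 4 air rats) and Ckm fell (-2.73 ± 0.74, detected in 1 of 8 silica rats), 2 and 1 adjusted over the list alone, with median 0.05 and mean -0.34 (camera adjusted p = 0.487, adjusted p = 0.553 with an estimated correlation). Of 7 erythroid genes 2 fell, 2 adjusted over the list alone, the hemoglobin gene Hbb-b1 (-0.37 ± 0.13) and the heme synthesis gene Alas2 (-0.42 ± 0.15). Each lost its call without any 1 of 5 rats (-0.33 and -0.30 at the least), Hbb-b1 also with median scaling (-0.40), both with array weights (-0.33 and -0.35), and Alas2 with no detection filter and, in a setting chosen after seeing the data, without the 5 air arrays of 1 run of the deposited order (-0.43). The list had median 0.02 and mean -0.12 (camera adjusted p = 0.694, adjusted p = 0.809 with an estimated correlation).

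**Figure D2:**
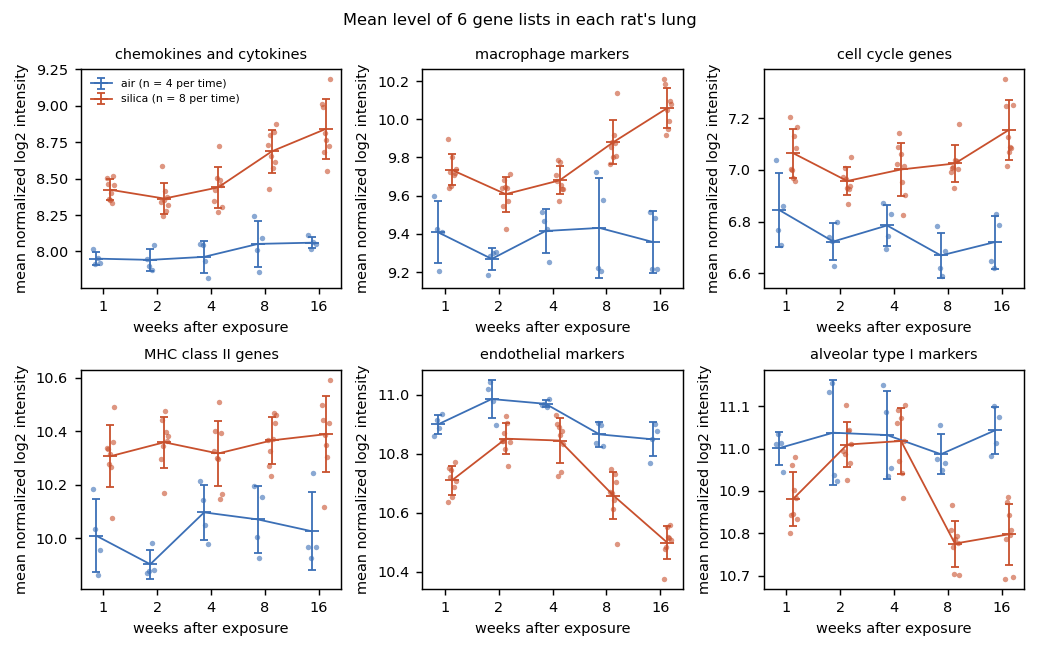
Mean normalized log2 intensity over the members of 6 gene lists in each rat (points) against weeks after exposure, with the mean ± SD of air rats (blue, n = 4) and silica rats (orange, n = 8). The chemokine mean was higher in silica rats by 0.47 at 1 week and 0.78 at 16 weeks, and the endothelial mean was lower by -0.19 and -0.35.

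Some genes of interest did not pass at any time. At 16 weeks the differences were 0.24 ± 0.13 for Timp1, an inhibitor of matrix proteases, 0.27 ± 0.15 for Nos2, 0.10 ± 0.10 for Tnf, -0.13 ± 0.10 for the collagen gene Col1a1, 0.01 ± 0.07 for surfactant protein gene Sftpc and 0.03 ± 0.06 for the club cell gene Scgb1a1. Il1b rose at 16 weeks by 0.44 ± 0.11, with the call lost under median scaling (0.38).

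To ask how alike the responses were, the changes at the 5 times were compared. Called at all 5 times were 160 genes that were higher and 13 that were lower, Dlk1 and Tac1 among the latter, and 4098 genes were called at 1 or more times. The 160 and 13 were 57 and 7 with median scaling, 93 and 4 with each time fitted alone, 42 and 2 by the stricter rule and, in a setting chosen after seeing the data, 48 and 2 with Nr1d1 and Bmal1 as covariates. The 13 were 24 with the authors' values. They were 7 without air replicate 4 of week 1, 8 without air replicate 4 of week 2, and 6 and 7 without air replicates 3 and 4 of week 4. In settings chosen after seeing the data they were 30 with the run as a block, 8 without the 5 air arrays of 1 run and 8 with the liver mean as a covariate. Across all genes the changes correlated between times with r from 0.31 (4 and 16 weeks) to 0.78 (8 and 16 weeks), with a median of 0.51. Among genes called at either time the median was 0.797. At 8 and 16 weeks 609 genes were higher at both, against 69.5 expected from the counts, and 475 were lower at both, against 70.6. Only 23 genes were called in opposite directions, among them 5 clock genes. Nr1d1 was lower at 1, 4, 8 and 16 weeks (-1.57, -1.68, -1.79 and -1.72) and higher at 2 weeks (1.90). Bmal1 fell at 2 weeks (-0.69 ± 0.09) and rose at 4 weeks (0.33 ± 0.09). The clock repressor Cry1 fell at 2 weeks (-0.75 ± 0.11) and rose at 1, 4 and 8 weeks (0.50, 0.62 and 0.44). Nfil3 fell at 2 weeks (-0.46 ± 0.08) and rose at 1, 4, 8 and 16 weeks (0.37, 0.35, 0.38 and 0.22). Tef rose at 2 weeks (0.55 ± 0.14) and fell at 1 and 8 weeks (-0.49 and -0.53). At 16 weeks 5 of 14 clock genes rose, among them Bhlhe40 (0.54 ± 0.08) and Per1 (0.84 ± 0.28, 7 of 8, named after its value was seen), and 1 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.0974, adjusted p = 0.111 with an estimated correlation).

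**Figure D3:**
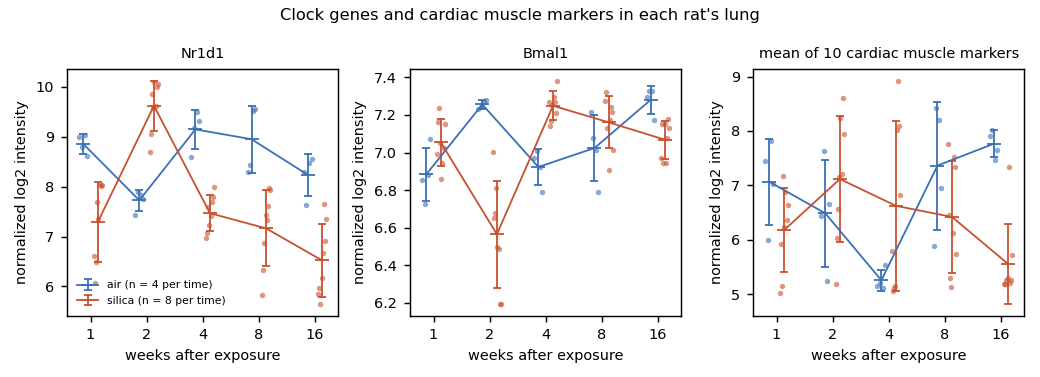
Normalized log2 intensity of Nr1d1, of Bmal1 and of the mean of 10 cardiac muscle markers in each rat (points) against weeks after exposure, with the mean ± SD of air rats (blue, n = 4) and silica rats (orange, n = 8). Nr1d1 was higher in silica rats at 2 weeks only (1.90), and the cardiac mean was lower by -2.21 at 16 weeks.

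The series title speaks of progression, so the change of the silica effect with time was tested directly. By the slope per doubling of weeks, the effect grew most for Spp1 (0.65 ± 0.12, n = 60), Ccl7 (0.59 ± 0.06), Lpo (0.45 ± 0.05), Cxcl11 (0.41 ± 0.10), Ccl2 (0.39 ± 0.07), LOC497762 (0.39 ± 0.04), LOC500159 (0.37 ± 0.09), Ighg (0.35 ± 0.08), LOC499078 (0.35 ± 0.06) and Retnla (0.34 ± 0.08). Further positive slopes were those of S100a8 (0.30 ± 0.04) and the fatty acid carrier Fabp4 (0.33 ± 0.06). The slope was most negative for Nr1d1 (-0.40 ± 0.11), Exoc3l1 (-0.21 ± 0.05), Ly49s4 (-0.18 ± 0.05), Fbp1 (-0.18 ± 0.05), Cavin1 (-0.17 ± 0.05), Mycn (-0.15 ± 0.04), Moxd1 (-0.15 ± 0.04), Plcb1 (-0.15 ± 0.04), the mast cell receptor Kit (-0.15 ± 0.04) and Igfbp3 (-0.14 ± 0.03). Of these only Exoc3l1 and Igfbp3 kept their calls without any 1 rat, whereas Mycn lost it without any 1 of 38 rats, Kit of 34, Nr1d1 of 25 and Cavin1 of 23. Moxd1 and Fbp1 lost it without any 1 of 4 rats, Ly49s4 of 2 and Plcb1 of 1. Of the positive slopes, that of Retnla lost its call without air replicate 1 of week 1 (0.29) and that of Cxcl11 without air replicate 3 of week 16 (0.38). For Slc26a4 (0.31, adjusted p = 0.0819), Mmp12 (0.30, adjusted p = 0.0914), Lcn2 (0.14, adjusted p = 0.322) and Cxcl6 (0.16, adjusted p = 0.316) no trend was shown. Neutrophil markers were the 1 list of 13 whose trend also passed with an estimated correlation (3 of 13 members up, 5 adjusted over the list alone; adjusted p = 0.0344 with an estimated correlation). Macrophage markers (4 of 24 up, 6 adjusted over the list alone) had adjusted p = 0.151 with an estimated correlation.

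In all 246 genes had a trend, 138 up and 108 down, and the effect of 291 genes differed among the 5 times by an F-test. The calls depended on the last time: without week 16 only 3 genes passed, and of the 22 slopes named only Exoc3l1 (-0.35) kept its call. The slopes left then were 0.18 for Spp1, 0.37 for Ccl7, 0.15 for Lpo, 0.14 for Cxcl11, 0.28 for Ccl2, 0.22 for LOC497762, 0.31 for LOC500159, 0.19 for Ighg, 0.22 for LOC499078, 0.0922 for Retnla, 0.26 for S100a8 and 0.12 for Fabp4. They were -0.42 for Nr1d1, -0.13 for Ly49s4, -0.0325 for Fbp1, -0.19 for Cavin1, -0.0931 for Mycn, -0.11 for Moxd1, -0.0894 for Plcb1, -0.19 for Kit and -0.14 for Igfbp3. All kept their direction. Without week 1 there were 461 genes, but the calls of Ighg (0.41), Exoc3l1 (-0.13), Ly49s4 (-0.21), Cavin1 (-0.22) and Igfbp3 (-0.12) ended. Without week 2 those of Cxcl11 (0.38), LOC500159 (0.33), Nr1d1 (-0.0460), Cavin1 (-0.15), Mycn (-0.12), Moxd1 (-0.15), Plcb1 (-0.11) and Kit (-0.0832) ended. Without week 4 those of Nr1d1 (-0.40), Fbp1 (-0.18), Cavin1 (-0.17), Mycn (-0.15) and Kit (-0.15) ended. Without week 8 those of Nr1d1 (-0.34), Exoc3l1 (-0.18), Ly49s4 (-0.17), Cavin1 (-0.15), Mycn (-0.16) and Kit (-0.11) ended. The count of trends was 53 with median scaling, which turned the share of upward slopes from 56.1% to 88.7%. It was 72 at an adjusted p under 0.01, 1.4e+02 without air replicate 4 of week 16, and 157 and 156 without air replicates 1 and 4 of week 1. The count of genes whose silica effect differs among the 5 times was 55 with median scaling, 85 at an adjusted p under 0.01, 174 without air replicate 2 and 188 without air replicate 4 of week 16. With settings chosen after seeing the data, the trend and F-test counts were 628 and 872 with the run of the deposited order as a block, 118 and 124 without the 5 air arrays of 1 run, and 133 and 59 with Nr1d1 and Bmal1 as covariates. With the cardiac mean as a covariate the F-test count was 101.

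Air rats were compared over the same weeks to show what moved without silica. Matrix genes fell: Col1a1 by -0.31 ± 0.03 per doubling of weeks (n = 20), Eln, which encodes elastin, by -0.30 ± 0.03, Col15a1 by -0.23 ± 0.03 and Col3a1 by -0.20 ± 0.02. In the list 15 of 35 fell, 21 adjusted over the list alone (camera adjusted p = 2.50e-29, and adjusted p = 1.16e-09 with an estimated correlation). Cyp1a1, which metabolizes aromatic hydrocarbons, fell by -0.56 ± 0.05, Akr1c3 by -0.29 ± 0.06 and Scn3b by -0.25 ± 0.03. The largest upward slopes were those of Acot1 (0.31 ± 0.06), the interferon-induced chemokine Cxcl9 (0.23 ± 0.03), the cytotoxic cell protease Gzmc (0.20 ± 0.05), Tmeff2 (0.19 ± 0.04) and Klra1 (0.19 ± 0.05). NK and cytotoxic cell markers rose in 2 of 13 cases, 5 adjusted over the list alone, and neutrophil markers in 0 of 13, 4 adjusted over the list alone (both adjusted p = 0.0497 with an estimated correlation, and 0.053 with the cardiac mean as a covariate, chosen after seeing the data). Of 12 lists passing camera 3 passed with an estimated correlation. In all 273 genes passed, 170 of them down. The count was 84 with median scaling, 126 at an adjusted p under 0.01, 1.8e+02 without air replicate 2 of week 1, and 1.5e+02 and 173 without air replicates 1 and 2 of week 16. With settings chosen after seeing the data it was 537 with the run as a block and 169 without the 5 air arrays of 1 run, and in the latter the calls of Gzmc (0.09) and Klra1 (0.13) ended. They also ended without air replicate 3 of week 16 (0.09 and 0.13).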

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

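The tests of the cardiac, clock and file-order patterns were chosen after the result was seen, except the comparison of mixing with scaling. The search for samples apart, the test of differences among times and the splits over all samples were set beforehand, the splits within runs afterwards.

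In 520 groups of values 35 samples lay far from the others of their group (6.73%), where chance flags about 1 in 20 groups. Given as log2, with the median of the others in brackets, they were as follows. Air rats at 1 week: ciliated cell genes in replicate 2, 7.20 (7.64), Cxcl6 in replicate 1, 5.30 (4.94), and the mean of liver genes in replicate 2, 5.72 (5.16). Silica rats at 1 week: neutrophil markers in replicate 8, 6.61 (6.42), antioxidant genes in replicate 6, 11.25 (11.34), and Spp1 and Sftpc in replicate 1, 9.59 (7.77) and 14.48 (14.07). Air rats at 2 weeks: macrophage markers, interferon-stimulated genes and Spp1 in replicate 1, 9.18 (9.30), 8.76 (8.46) and 5.72 (7.17), MHC class II genes in replicate 3, 9.98 (9.88), and the liver mean in replicate 4, 4.82 (4.76). Silica rats at 2 weeks: mast cell markers in replicate 2, 6.75 (6.21), interferon-stimulated genes in replicate 4, 8.13 (8.42), and Arg1 in replicate 5, 8.94 (9.44). At 4 weeks: interferon-stimulated genes in air replicate 3, 8.65 (8.46), inflammasome and NF-kB genes in air replicate 1, 8.92 (8.80), and in silica replicate 6 clock genes, 7.27 (7.19), and the number of genes detected, 11388 (12292). At 8 weeks: in silica replicate 8 macrophage markers, 10.14 (9.85), complement genes, 10.23 (9.97), cell cycle genes, 7.18 (7.01), lysosome genes, 10.83 (10.62), and Nos2, 5.71 (5.02), and in silica replicate 1 adipocyte markers, 6.94 (6.40), and the liver mean, 8.37 (5.23). Air rats at 16 weeks: mesothelial markers and Timp1 in replicate 4, 7.60 (7.33) and 10.76 (10.46), MHC class II genes in replicate 3, 10.24 (9.97), and S100a8 in replicate 1, 10.86 (10.62). Silica rats at 16 weeks: club and secretory cell genes and cardiac markers in replicate 5, 11.07 (10.00) and 7.34 (5.26), endothelial markers in replicate 1, 10.38 (10.51), Timp1 in replicate 6, 10.23 (10.78), and the number of genes detected in replicate 3, 11257 (12134).

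For 29 of 73 named genes the silica effect differed among the 5 times by the F-test of the interaction. The limma adjusted p-values were 0.000973 for Ccl2, 4.25e-09 for Ccl7, 0.000103 for Spp1, 0.000255 for S100a8, 0.00838 for Retnla. They were 4.29e-07 for Nr1d1, 0.0298 for Col4a3, 2.15e-05 for Ceacam4, 0.000490 for Tmem45b, 2.46e-11 for Lpo and 0.0181 for Cxcl11. For the heart muscle genes they were 0.0360 (Myh6), 0.0320 (Myl7), 0.0497 (Tnni3 and Tnnt2) and 0.0381 (Csrp3). Further values were 6.11e-08 for LOC497762 and Cry1, 0.0364 for Ighg, 0.00127 for LOC499078. They were also 0.00762 for Exoc3l1, 0.0340 for Ly49s4, 0.0225 for Fbp1, 0.0195 for Plcb1, 0.00581 for Kit, 0.0206 for Igfbp3, 6.83e-07 for Bmal1, 0.00186 for Tef and 5.31e-07 for Nfil3.

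Cardiac muscle markers were lower in silica rats at 16 weeks. Their deviations from the group means rose and fell together over 60 rats (mean correlation 0.57; 0.527 in air and 0.592 in silica rats, lowest pair -0.171), which is in line with a varying amount of heart muscle in the sampled tissue. The SD of their mean within groups was 0.95 against a median of 0.105 for the other lists. A silica effect of the same direction at every time stays open, since the mean was lower at 3 of 5 times. Whether the air rats of 16 weeks stood apart from other air rats also stays open (difference 1.22, exact permutation p = 0.0512 over 4845 splits). The silica rats of 16 weeks were lower than other silica rats by -1.03 (permutation p = 0.0228 from 1e+05 resamples).

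Of 14 clock genes 5 (Bmal1, Cry1, Tef, Nr1d1 and Nfil3) were called in opposite directions at 2 weeks and at other times, while Per2, Bhlhe40 and Bhlhe41 were called higher at both 2 and 16 weeks. Over the 14 clock genes the change at 2 weeks correlated at -0.747 with the mean change at the other times, but at -0.201 without Nr1d1, and this correlation restates the pattern itself. Nr1d1 tended to rise with replicate number within silica groups, an order seen afterwards and not tested. At 1, 2 and 4 weeks replicate 1 had 6.61, 8.70 and 6.97 and replicate 8 had 8.04, 10.05 and 8.00. At 8 and 16 weeks they had 5.83 and 5.84 against 7.94 and 7.34. Air rats lay below the silica rats at 2 weeks (7.42 to 7.89) and above them at 8 weeks (8.30 to 9.55). Whether replicate numbers follow the order of killing is not given. Whether air and silica rats were killed at different times of day therefore stays open. For the 5 genes the opposite calls show that the difference from air rats did not keep the same direction at every time. These calls are the pattern itself and no separate test of its cause. The time of killing is not given in the sources used here, and within groups Nr1d1 and Bmal1 correlated at -0.359.

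Silica-response genes (Slc26a4, Lcn2, Ccl2, Cxcl1, Mmp12 and Noxo1) were higher in the 5 air rats of the sixth run of arrays in the deposited order, by 0.544 over their group means (0.306 to 0.905, 5 of 5 above). This compares with -0.284, -0.0175 and -0.243 in the other runs with air rats and 0.00241 in the 5 silica rats of that run (3 of 5 above). The 6 genes are those in which the pattern was seen, so the placement was tested on the other genes called at all times: their signed mean deviation in these 5 air rats was 0.142 (5 of 5 above), against -0.0441, -0.0304 and -0.0672 in the other runs. The exact permutation p was 0.0156 over 331776 placements. It comes from the same rats and from genes of the same response, so it is no independent check, and chance placement stays open. Over the other genes called at all times, a mixture with silica RNA (fitted share 17.6%) left 1.32 times the squared error of a weaker form of the whole response (fitted factor 0.257). The ratio the other way was 0.756, and neither ratio has a measure of spread. The deviations and the silica effects were both taken from the same other air rats, which ties them together. Mixing and the weaker form therefore cannot be told apart. The 13 genes lower in silica rats, taken by themselves, lay closer to mixing (median -0.0181 against -0.0682 predicted under mixing and -0.113 under the weaker form, 9 below the other air rats, while 149 of the higher genes lay above with a median of 0.175). What raised these genes in air rats stays open, and no biological explanation was tested beyond the form of the response.

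The real groups were set against 100 splits of the same samples, the real one included. For the counts of genes the share of splits as large was under 0.05 at every time. At 1 week there were 532 genes against 114 in the highest other split (1 split as large). At 2 weeks it was 1304 against 1719 (2 splits) and at 4 weeks 924 against 338 (1 split). At 8 weeks it was 1241 against 181 (1 split) and at 16 weeks 3159 against 1377 (1 split). The same holds for the air trend (273 against 1200, 3 splits). These splits moved arrays freely, although arrays deviated together within runs of the deposited order. Such a share alone therefore does not exclude chance. For the trend (246 against 417, 2 splits) and the F-test (291 against 7, 1 split) the splits moved silica and air labels. They break a constant silica effect too, so they cannot tell whether a change of the effect with time arose by chance. What lay behind the splits with 1719 and 1200 genes was not tested. For the counts of gene lists the share was under 0.05 at 1 week (20 against 19, 1 split) and 4 weeks (18 against 18, 3 splits). There other splits came close to or reached the real count, so chance stays open for the lists too. The share was not under 0.05 at 2 weeks (15 against 17, 6 splits), 8 weeks (17 against 19, 12 splits) or 16 weeks (18 against 19, 10 splits). Nor was it for the trend (13 against 18, 18 splits) or the air trend (12 against 14, 9 splits).

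The splits above ignore the runs of the deposited order, within which arrays deviated together, so labels were also moved within runs only. At a single time this gives 16 splits, too few for a share under 0.05. From the first time to the last the highest other split had 2.2e+02, 865, 266, 398 and 1146 genes against the real 532, 1304, 924, 1241 and 3159 (1 split as large at each time). For lists it had 18, 18, 19, 18 and 19 against 20, 15, 18, 17 and 18 (1, 4, 3, 4 and 6 as large). The share under 0.05 for lists at 4 weeks thus rests on the splits over all samples alone. With 100 splits chance within runs can be excluded for the gene count of the air trend (273 against 120, 1 as large). For the trend (246 against 986, 3 as large) and the F-test (291 against 866, 3 as large) silica and air labels again changed places. These splits therefore cannot decide either. What lay behind the splits with 986 and 866 genes was not tested either. For lists the share within runs was under 0.05 for the air trend (12 against 13, 3 as large), unlike over all samples, so chance stays open there. It was not under 0.05 for the trend (13 against 21, 40 as large).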

How the results depend on the processing

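Chosen after the result was seen were the file-order run as a block, the covariates, leaving out the arrays of 2 runs, and the counts at all 5 times; all other alternatives were planned. A block for the slide was not run, since the files name no slide. Of the other results 26211 stayed on their side of the threshold, among them any that changed direction without a call in either setting. In 1831 the direction was kept but not the call, 5 reversed with a call in either setting, and the rest passed newly. The 5 arrays with fewest detected genes, no background correction, normexp without controls, detection filters, robust eBayes and the mean of lines moved no count over 1.5 times. Dim genes near background and the 4 air arrays per time limit what can be seen. Unless said, the cause was not tested.

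With median scaling the gene counts were 141, 692, 422 and 2005 at 1, 2, 8 and 16 weeks (532, 1304, 1241 and 3159 as reported), 55 for the F-test (291), 53 for the trend (246) and 84 for the air trend (273), and 9 lists passed at 4 weeks (18). The share of higher calls was then 24.4% at 2, 11.4% at 4 and 64.5% at 8 weeks, 88.7% for the trend and 25.0% for the air trend. As reported it was 51.2%, 43.1%, 53.4%, 56.1% and 37.7%. With cyclic loess it was 61.4% at 2, 56.0% at 4 and 52.0% at 16 weeks. At 16 weeks it was 39.9% with median scaling and 46.2% as reported. At 4 weeks median scaling reversed Cfb (-0.0223), Npc2 (-0.0585), Abcg1 (-0.00186) and RT1-Da (-0.10), and Ncf1 reversed in the trend without week 16 (-0.0337). Array weights gave 746 at 2 weeks. Fits of only the 2 groups, with fewer samples, gave 413, 444 and 778 at 2, 4 and 8 weeks. The stricter rule by its construction left 73, 113, 80, 1.6e+02 and 392 genes, and an adjusted p under 0.01 left 85 (F-test), 72 (trend) and 126 (air trend). The trend had 461 genes without week 1 and 3 without week 16. The median correlation between times was 0.797 over called genes only (0.51 over all), chosen for large changes.

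The file-order run as a block gave 872 (F-test), 628 (trend) and 537 (air trend). Without the 5 air arrays of the sixth run, which selects on the genes compared, it was 476 at 2 weeks, 124, 118 and 169. The cardiac covariate gave 101 (F-test), the liver covariate 574 at 4 weeks, and Nr1d1 with Bmal1 (of which Nr1d1 differs between the groups at all times) 104, 438, 720 and 1636 at 2, 4, 8 and 16 weeks, 59 (F-test) and 133 (trend). The 16 week count was 2.42 times the next highest as reported, 1.64 at the least with other scalings, 1.89 with the cardiac and 2.27 with the clock covariates.

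With an estimated correlation 11, 2, 2, 11 and 11 lists passed, 1 for the trend and 3 for the air trend (20, 15, 18, 17, 18, 13 and 12 with the preset). With the cardiac covariate as well it was 4 at 2 and 5 at 4 weeks, 1 (trend) and 1 (air trend), and with the liver covariate 11 at 1, 2 at 2 and 4 and 11 at 16 weeks, 1 (trend) and 3 (air trend). Fry gave 8 for the trend and 3 for the air trend. Leaving out 1 rat gave 2.3e+02 to 630, 469 to 1905, 241 to 1453, 701 to 1364 and 2407 to 3133 genes at the 5 times. It gave 174 to 429 (F-test), 1.4e+02 to 294 (trend) and 1.5e+02 to 372 (air trend). For lists it gave 17 to 21, 14 to 17, 16 to 19, 17 to 18 and 18 to 19 lists, 12 to 15 (trend) and 8 to 16 (air trend).

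Called at all 5 times were 160 higher and 13 lower genes. These were 57 and 7 with median scaling, 93 and 4 with only the 2 groups compared, 42 and 2 by the stricter rule, and 48 and 2 with Nr1d1 and Bmal1. The lower genes were 24 with the authors' values, 30 with the run block, 8 without the 5 air arrays of the sixth run and 8 with the liver covariate. Leaving out 1 rat gave 1.1e+02 to 170 higher and 6 to 19 lower genes.

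Replicate numbers do not pair the rats: same-numbered deviations correlated at -0.078 to 0.050 on average, over 0.1 in 0 to 2 of 4 pairs per time. With the replicate block the counts were 623, 1139, 857, 1343 and 3219 genes, 369 (F-test), 309 (trend) and 293 (air trend), and 20, 15, 18, 18 and 18 lists, 13 (trend) and 12 (air trend).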

Other observations

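All values here were chosen after the results were seen. Beyond the lists, 6 genes of the response varied between air rats more than between silica rats: the pooled SD within groups was 0.833 against 0.294 for Slc26a4, 0.528 against 0.219 for Lcn2, 0.792 against 0.329 for Mmp12 and 0.496 against 0.161 for Noxo1. For Ccl2 it was 0.491 against 0.270 and for Cxcl1 0.396 against 0.226. These 6 genes moved together within groups, with a mean pairwise correlation of 0.775 in air and 0.447 in silica rats. Of the 160 genes higher at all 5 times 121 had the larger SD in air rats (median ratio 1.28), as had 9 of the 13 lower at all times. Ccl7 went the other way, with 0.273 in air and 0.351 in silica rats.

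The 13 genes lower at all 5 times were Alox15, Ascl2, Cd93, Dlk1, Ecm1, Jup, Kif4a, LOC497781, LOC500201, Map4, Tac1, Tesc and Xpnpep2. Alox15, a lipoxygenase, and Cd93, a receptor of endothelial and myeloid cells, stand beside the neuropeptide precursor Tac1.

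Arrays next to each other in the deposited order deviated together: the mean correlation of deviations from the group means was 0.196 within the 8 runs and -0.0306 between runs. The fewest genes were detected in the seventh run, 5 silica arrays with a mean of 11390.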
